A study of Rattus norvegicus with 30 samples.

How the data were processed

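Total RNA of 30 cultures was measured, 5 wells for each of 6 groups defined by agent, concentration and harvest time, per the labels' protocols, which call the cultures independent. Which wells shared a plate is not given in the sources used here. If a plate held 1 group only, plate and group cannot be separated. The cells were frozen male Sprague Dawley rat hepatocytes from a single supplier, plated on collagen, overlaid with Matrigel and dosed on day 3. Water was the vehicle. How many donor animals the cells came from is not given in the sources used here, so p-values measure the spread between cultures. RNA was labelled with biotin and hybridised to 1 array per culture, per the labels' protocols. The series is part of a larger study of 10 compounds, each run with its own vehicle controls. Only the valproate cultures and their controls were used here.

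The deposited values are signal intensity on a linear scale, 1 per probeset and array, per the file headers. The authors used MAS5, per the submitters' processing notes, and its version and settings are not given in the sources used here. The mean signal of each array after trimming lay between 1500.5 and 1500.7, so the arrays had been scaled to one level before deposit, and that scaling was kept. Scaling of this kind sets the total of every array equal, so a change of most genes in one direction would be hidden. Signal of probesets that match related genes can be shared between them, as for the acyl-CoA thioesterases.

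Of 31099 probesets, 57 were control probesets and were left out. The platform table gave 1 gene symbol for 20826 probesets, several for 436 and none for 9780, and 20758 were matched to the rat gene table by their gene identifier. No gene was named from a probeset with several symbols. Signals were turned into log2(signal + 16), which understates the change of dim probesets. Probesets with a mean at or above the 30th percentile were tested, 21729 in all. Each of 14217 genes was represented by its probeset with the highest mean, and 11604 of these passed the filter.

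All 6 groups entered 1 linear model in limma 3.58.1 under R 4.3.3 (lmFit, then eBayes with a trend), with 24 residual degrees of freedom. The comparisons were each dose against water at each time, the difference of each effect between 48 h and 24 h (interaction), 10 mM against 0.5 mM at each time, and 48 h against 24 h in water. Tests were two-sided and p-values were adjusted by Benjamini-Hochberg over all probesets of a comparison. A change was called at an adjusted p under 0.05 with no fold minimum. A set of 35 gene lists was tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the lists, with an estimated correlation and with fry beside it. Camera compares a list with the other genes. Fry asks whether the genes of a list move, on balance, one way, and compares them with no other genes. The lists covered lipid, bile acid, amino acid, glucose and drug metabolism, stress responses, plasma proteins, cell cycle, chromatin, neuronal genes and 4 sets of markers of other liver cells. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

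The groups, comparisons, tests, gene lists, rule for naming genes and the main alternatives were fixed before the data were examined. The rule named, for each dose against water, the 8 largest rises and 8 largest falls among called genes with 1 symbol that is no placeholder, values that do not overlap between the groups and a mean in the higher group at or above the median of probesets. It added up to 4 called members of each list with a camera call or at least 50% of members called, and of lists on beta-oxidation, PPARalpha, CAR and PXR, deacetylase inhibitors, the urea cycle and other cell types. For the interactions and the time comparison it named up to 5 genes per direction, with no rule on overlap for the interactions. A fixed set of genes was always named, of which Cyp2b1 and H1f0 were not analysed here and some others are not reported here. Cyp7a1 and Fasn in the interactions, and Cyp7a1, Cyp1a1, Cyp4a1 and Fgf21 between the doses, were added after their values were seen. So were the tests of gene lists on the interactions and the genes named with the oxygen-responsive list.

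The alternatives fixed in advance were pseudocounts of 1 and 64, quantile normalization, centring on ribosomal protein genes, no filter and a filter at the 50th percentile, no trend, only the compared groups, array weights, a fold minimum of 2, the mean of the probesets of a gene, leaving out each array, splitting the water cultures for the correlation of the doses, and a block for each run of 6 arrays in the running number of the titles. RNA quality was measured by the log2 ratio of the 3' to the 5' control probesets of actin and GAPDH. Alternatives chosen after seeing the data were these ratios as covariates, leaving out the 3 or the 5 arrays with the highest actin ratio, and scores of the arrays on the first residual components (3 fits).

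The model was tested on simulated data for 10 mM against water at 24 h with 21729 probesets. It found 40.3% of 67 changes of 0.5 on the log2 scale, 71.6% of 67 changes of 1 and 95.5% of 66 changes of 2, with 15 false calls among 153. Over 20 further draws a mean of 4.52% of calls were false (1.32 to 9.4%). Of 35 lists on 11604 simulated genes, camera called the 1 shifted and 0 others, and fry 0 others. Correlated genes were not covered.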

Results

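Primary hepatocytes of male Sprague Dawley rats, thawed from frozen stocks and kept on collagen under a Matrigel overlay, were dosed on day 3 with water or with sodium valproate, a branched short-chain fatty acid used against epilepsy and an inhibitor of histone deacetylases. The 30 samples form 6 groups of 5 cultures, which are water, 0.5 mM valproate and 10 mM valproate at 24 h and at 48 h. RNA was read on a 1-colour oligonucleotide array, and 21729 probesets representing 11604 genes passed the filter on signal. The number of arrays limits the precision of every value. Changes are given on the log2(signal + 16) scale with the standard error of the fit (n = 5 per group), positive when the first-named group is higher. The first principal component held 39.2% of the variance and separated the 10 mM cultures from all others. Replicates correlated with each other at a median of 0.969 across probesets. No pair of arrays correlated above 0.976, so none was counted as a repeat of another.

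RNA quality was not even across the arrays. The log2 ratio of the 3' to the 5' probeset of beta-actin, which rises as RNA breaks down, was 1.75 ± 0.58 (SD, n = 5) in water at 24 h, 1.29 ± 0.09 with 0.5 mM and 1.44 ± 0.07 with 10 mM. At 48 h it was 1.23 ± 0.06 in water, 1.82 ± 0.69 with 0.5 mM and 1.41 ± 0.09 with 10 mM. The arrays above 2 were replicate 3 of water at 24 h and replicates 3 and 4 of 0.5 mM at 48 h.

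**Figure D1:**
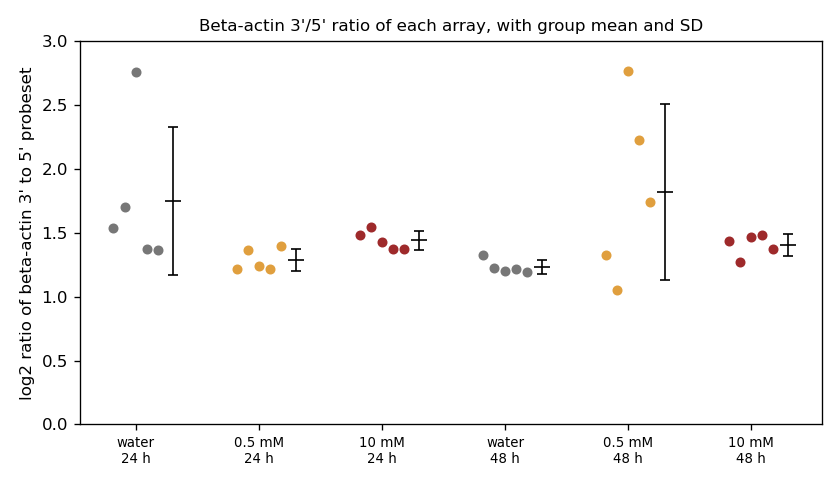
Log2 ratio of the beta-actin 3' to 5' probeset (vertical axis) for each array, by group (horizontal axis), with group mean and SD as bars beside the 5 points. The highest points are 1 water array at 24 h and 2 arrays of 0.5 mM at 48 h, all above 2.

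The first comparison asked what a high dose of valproate does to hepatocytes within a day. At 10 mM and 24 h, Acot1, an acyl-CoA thioesterase, rose by 5.42 ± 0.33 (adjusted p = 7.56e-15). Hamp, which encodes the iron hormone hepcidin, rose by 4.27 ± 0.11, from a signal of 2583 ± 147 in water to 50155 ± 4117 (SD, n = 5). Soat1, which esterifies cholesterol, rose by 5.18 ± 0.37, and Nefm, a neurofilament subunit, by 3.95 ± 0.23. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell by 3.60 ± 0.20 (adjusted p = 1.34e-15), and Baat, which conjugates bile acids, changed by -3.45 ± 0.17. Among the other genes whose 5 treated and 5 water values did not overlap were Cd24 (5.28), Crip1 (4.90), Naaa (4.09) and Mcub (3.90) upward and Asb5 (-4.07), Tmed1 (-3.75), Mab21l3 (-3.63) and Chdh (-3.41) downward. Mean log2 values in water of Acot1, Soat1, Nefm, Cd24, Crip1, Naaa, Mcub, Snap91 and Bhlhe41 lay under the level of the filter, so the size of these rises is uncertain. That of Acot1 was 5.63 with a pseudocount of 1 and 4.93 with 64.

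Of the 35 gene lists, bile acid synthesis and transport had the lowest camera p at 10 mM and 24 h. Of its 22 measured members 20 were lower and 0 higher, with a median change of -1.66 (camera adjusted p = 1.01e-12, and adjusted p = 0.0292 with an estimated correlation). They included the transporters Abcc3 (-2.84) and Slco1a4 (-2.82). Amino acid catabolism fell with 26 of 30 members lower (camera adjusted p = 2.62e-11, and adjusted p = 0.0349 with an estimated correlation), among them Ftcd and Hal of histidine breakdown (-2.93 and -2.58), Mat1a, which makes S-adenosylmethionine (-2.59), and Sardh (-2.51). In the urea cycle list 8 of 11 members were lower, including Otc (-1.87), Arg1 (-1.45) and Slc25a15 (-1.90), and Cps1 changed by -0.39 ± 0.05 (camera adjusted p = 0.000824, and adjusted p = 0.092 with an estimated correlation). Cholesterol synthesis had 15 of 19 members lower, with Idi1 (-1.26) and Sqle (-1.21) (camera adjusted p = 3.63e-06, and adjusted p = 0.048 with an estimated correlation). Constitutive P450s fell too (18 of 23 lower), with Cyp2f4 at -2.92 and Cyp2a2 at -2.16 (camera adjusted p = 6.17e-07, and adjusted p = 0.0349 with an estimated correlation).

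Lipid genes split at 10 mM and 24 h. Fasn, the fatty acid synthase, changed by -2.29 ± 0.12 and Acaca, which makes malonyl-CoA, by -2.04 ± 0.09, and 13 of 22 members of the fatty acid synthesis list were lower (camera adjusted p = 0.000992, and adjusted p = 0.149 with an estimated correlation). In the mitochondrial beta-oxidation list 10 of 23 measured members were higher and 10 lower, with Acsl1 at 0.87 and Acadvl, which starts the oxidation of very long chains, at -1.41 (camera adjusted p = 0.446). Of the PPARalpha and peroxisomal targets 12 were higher and 11 lower of 25 (camera adjusted p = 0.352), with Pdk4 (3.24), Angptl4 (1.60), Ehhadh (1.40) and Cyp4a1 (1.36) upward. Cpt1a, the entry step of mitochondrial beta-oxidation, rose by 0.72 ± 0.12, the lipid droplet coat gene Plin2 by 0.15 ± 0.06 and the hormone gene Fgf21 by 0.84 ± 0.12.

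Cell cycle genes rose at 10 mM and 24 h, with 16 of 29 members higher and 1 lower (camera adjusted p = 0.00428, and adjusted p = 0.0626 with an estimated correlation). They included the cyclins Ccne1 (2.27) and Ccne2 (3.05) and the replication helicase subunit Mcm4 (2.45). Of 24 neuronal genes 12 were higher and 0 lower (camera adjusted p = 0.0238, and adjusted p = 0.149 with an estimated correlation), among them Tubb3, a neuronal tubulin (2.46), and Snap91 (3.25). In the list of genes known to respond to histone deacetylase inhibitors 9 of 19 measured members were higher and 2 lower (camera adjusted p = 0.0781), with Tubb2b (3.29) and Cdkn1c (2.53) upward and Mt1, a metallothionein (-1.37), downward. Cdkn1a, the p21 gene, was at -0.32 ± 0.16 (adjusted p = 0.108). Hdac1, a target of the drug, rose by 2.27 ± 0.25, and 7 members of the deacetylase list were higher and 5 lower of 23 (camera adjusted p = 0.69). Atf3 and Ddit3, stress-induced transcription factors, rose by 2.35 ± 0.09 and 1.98 ± 0.09, and the ATF4 list as a whole had 11 higher and 12 lower of 29 (camera adjusted p = 0.46).

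Plasma protein genes fell unevenly at 10 mM and 24 h. Coagulation genes were lower for 17 of 20 members, with Serpind1, the heparin cofactor II gene, at -2.25 (camera adjusted p = 1.33e-05, and adjusted p = 0.125 with an estimated correlation). Complement and acute phase genes were lower for 21 of 27, with the lectin gene Mbl2 at -2.23 (camera adjusted p = 3.13e-06, and adjusted p = 0.092 with an estimated correlation). Alb, the albumin gene, was at -0.15 ± 0.08 (adjusted p = 0.14) and the fibrinogen gene Fgb at 0.12 ± 0.07 (adjusted p = 0.166). In water at 24 h the brightest named genes were Cyp3a23-3a1 (16.21), Arg1 (16.14), Alb (16.13), Fgb (16.06), Cps1 (15.94) and Plin2 (15.58). Whether that level compresses their changes was not tested. The nuclear receptor genes Nr1h3, the LXRalpha gene, and Nr1i3, the CAR gene, changed by -3.10 ± 0.14 and -1.76 ± 0.14, and 11 of 19 hepatocyte transcription factors were lower (camera adjusted p = 0.00928, and adjusted p = 0.0664 with an estimated correlation). CAR and PXR targets had 17 lower and 3 higher of 22 (camera adjusted p = 2.01e-05, and adjusted p = 0.048 with an estimated correlation), with Por, the P450 reductase gene, at -1.35 and Cyp3a23-3a1 at -0.19 ± 0.06. Cyp1a1, the main target of the aryl hydrocarbon receptor, changed by -1.62 ± 0.19. Lists called with the preset correlation only were also lipid droplets and lipid export (3 higher and 12 lower of 22), Nrf2 targets (2 higher and 17 lower of 22), glucose metabolism (5 higher and 11 lower of 18), secreted plasma carriers (2 higher and 13 lower of 20), dedifferentiation associated (3 higher and 13 lower of 21), oxidative phosphorylation (7 higher and 16 lower of 39) and glutathione conjugation (4 higher and 15 lower of 23), with adjusted p from 0.0626 to 0.622 with an estimated correlation. The carnitine and coenzyme A list, which holds Glyat of glycine conjugation (-2.58), had 14 of 24 members lower and 6 higher (camera adjusted p = 0.00793, and adjusted p = 0.048 with an estimated correlation).

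Among the lists without a camera call at 10 mM and 24 h were p53 targets (9 higher and 1 lower of 18), heat shock proteins (4 higher and 6 lower of 14), endoplasmic reticulum chaperones (7 higher and 5 lower of 22), branched-chain amino acid catabolism (9 higher and 10 lower of 20), circadian clock (6 higher and 3 lower of 16) and AhR targets (2 higher and 3 lower of 6), with camera adjusted p from 0.139 to 0.823. Examples were the heat shock gene Hspa1a (1.61), Gadd45a, a DNA damage gene (1.13), and the clock repressors Bhlhe41 (3.10) and Bhlhe40 (-2.13). Adjusted over the list alone, the counts of higher and lower members were the same except for mitochondrial beta-oxidation (11 and 10), fatty acid and triglyceride synthesis (4 and 15), lipid droplets and lipid export (4 and 13), cholesterol synthesis (1 and 15) and endoplasmic reticulum chaperones (8 and 5). Other exceptions were heat shock proteins (5 and 6), histone deacetylases and corepressor subunits (8 and 7), complement and acute phase (1 and 23), dedifferentiation associated (4 and 13), oxidative phosphorylation (8 and 16) and macrophage and Kupffer markers (1 and 9). Median, mean and test differed in sign for mitochondrial beta-oxidation (median 0.05, mean -0.11, camera direction down), heat shock proteins (median -0.05, mean 0.04, camera direction down) and branched-chain amino acid catabolism (median -0.17, mean 0.02, camera direction down). Leaving out a single array ended the camera call of secreted plasma carriers (without water replicate 5, adjusted p up to 0.0515) and oxidative phosphorylation (without 10 mM replicates 1 and 5 or water replicates 2, 4 and 5, adjusted p up to 0.0998). After quantile normalization camera no longer called secreted plasma carriers (0.309) and oxidative phosphorylation (0.575, direction turned). After centring on ribosomal protein genes camera no longer called oxidative phosphorylation (0.09). With the probesets of a gene averaged camera no longer called neuronal genes (0.0546) and oxidative phosphorylation (0.111). Values in these parentheses are adjusted p. Leaving out 1 array brought a call for Alb without water replicate 1 (-0.20), Fgb without water replicate 5 (0.17) and Cdkn1a without water replicates 4 and 5 (-0.40 and -0.41). The call of Cyp3a23-3a1 ended after centring on ribosomal protein genes (-0.15) and without the 5 arrays with the highest actin ratios (-0.16). With the probesets of a gene averaged Ccne2 stood at 1.70 and Cps1 at -0.72. After quantile normalization Cps1 stood at -0.21, Cyp3a23-3a1 at -0.09, Plin2 at 0.35 and Fgb at 0.27, all called. Plin2 lost its call without water replicates 1, 3 and 4 or 10 mM replicates 2, 4 and 5, with values from 0.11 to 0.19 over 10 removals, and was not called in 14 alternatives in all, the fold minimum aside. In all, 6085 probesets were higher and 4398 lower at 10 mM and 24 h, of which 2966 changed by at least 1 on the log2 scale. By gene the counts were 3611 higher and 2896 lower.

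After 48 h of 10 mM Acot1 rose by 7.12 ± 0.33, with values from 6.61 to 7.39 when 1 array was left out. Crip1 rose by 6.31 ± 0.22, Hamp by 4.83 ± 0.11 and Soat1 by 5.00 ± 0.37. Mean log2 values in water of Acot1, Crip1 and Soat1 lay under the level of the filter here too. The peroxisomal enzyme Ehhadh rose by 2.44 ± 0.12, Cyp4a1, a fatty acid omega-hydroxylase, by 1.95 ± 0.08, and of the PPARalpha and peroxisomal targets 16 were higher and 3 lower of 25 (camera adjusted p = 1.02e-06, and adjusted p = 0.0338 with an estimated correlation). Pck1, which makes phosphoenolpyruvate for gluconeogenesis, rose by 3.30 ± 0.20 (adjusted p = 1.36e-14). Falls were led by Car5a (-3.48), Defb1 (-3.49) and Asb5 (-3.35), Car5a being a mitochondrial carbonic anhydrase. In mitochondrial beta-oxidation 13 of 23 measured members were higher and 7 lower (camera adjusted p = 0.229), with Cpt1a at 0.89 ± 0.12 and Hadha at 0.77. Fgf21 rose by 1.54 ± 0.12 and Plin2 by 0.21 ± 0.06, and Fasn changed by -2.27 ± 0.12.

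At 10 mM and 48 h lower members numbered 16 of 22 for bile acids (camera adjusted p = 9.93e-08, and adjusted p = 0.0454 with an estimated correlation), with Cyp7a1 at -1.66 ± 0.20 and Slc27a5, a bile acid CoA ligase, at -2.18. For cholesterol synthesis they were 17 of 19 (camera adjusted p = 1.27e-07) and for amino acid catabolism 23 of 30 (camera adjusted p = 1.6e-07). For constitutive P450s they were 16 of 23 (camera adjusted p = 8.56e-06). With an estimated correlation adjusted p was 0.0338, 0.0539 and 0.0454. Coagulation (17 of 20 lower), complement (20 of 27) and fatty acid synthesis (17 of 22) were called with the preset correlation only. Each had adjusted p = 0.116 with an estimated correlation. Cell cycle genes (15 of 29 higher) and neuronal genes (9 of 24 higher) were also called only with the preset. Their adjusted p was 0.119 and 0.217 with an estimated correlation. Within them Ccne2 stood at 2.82, Nefm at 3.80 and Uchl1, a neuronal ubiquitin hydrolase, at 3.12. Urea cycle genes had 6 of 11 lower (adjusted p = 0.236 with an estimated correlation), with Otc at -1.29 and Cps1 at -0.27 ± 0.05. CAR and PXR targets went both ways, with 13 lower and 4 higher of 22 (adjusted p = 0.277 with an estimated correlation), including Cyp3a2 (1.82) and Cyp2b3 (1.46) upward. Alb was at -0.04 ± 0.08 (adjusted p = 0.743), Fgb rose by 0.51 ± 0.07, Cyp1a1 changed by -0.89 ± 0.19, Cyp3a23-3a1 by -0.20 ± 0.06 and Cdkn1a was at 0.12 ± 0.16 (adjusted p = 0.59). The deacetylase inhibitor list had 8 higher and 4 lower of 19 (camera adjusted p = 0.335).

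Other lists called at 10 mM and 48 h with the preset correlation only were Nrf2 targets (3 higher and 15 lower of 22), glucose metabolism (3 higher and 10 lower of 18), dedifferentiation associated (4 higher and 14 lower of 21), oxidative phosphorylation (7 higher and 20 lower of 39) and glutathione conjugation (4 higher and 16 lower of 23), with adjusted p from 0.116 to 0.498 with an estimated correlation. No camera call was made for p53 targets (8 higher and 4 lower of 18), heat shock proteins (6 higher and 5 lower of 14), endoplasmic reticulum chaperones (8 higher and 6 lower of 22), branched-chain amino acid catabolism (5 higher and 9 lower of 20), circadian clock (8 higher and 2 lower of 16), AhR targets (1 higher and 1 lower of 6), lipid droplets and lipid export (5 higher and 6 lower of 22), secreted plasma carriers (6 higher and 9 lower of 20), hepatocyte transcription factors (6 higher and 7 lower of 19), carnitine and coenzyme A (7 higher and 9 lower of 24), histone deacetylases and corepressor subunits (10 higher and 6 lower of 23) and ATF4 and amino acid response (8 higher and 11 lower of 29), with adjusted p from 0.186 to 0.801. They included Igfbp2, an insulin-like growth factor binding protein gene, at 2.97 and Hspb1, a small heat shock protein gene, at 1.81. Adjusted over the list alone, the counts of higher and lower members were the same except for PPARalpha and peroxisomal targets (17 and 3), lipid droplets and lipid export (5 and 7), bile acid synthesis and transport (2 and 17), other constitutive liver P450s (3 and 17), ATF4 and amino acid response (9 and 11) and endoplasmic reticulum chaperones (9 and 6). Other exceptions were heat shock proteins (7 and 5), urea cycle and ammonia (2 and 7), amino acid catabolism (3 and 23), complement and acute phase (3 and 21), hepatocyte transcription factors (8 and 8), oxidative phosphorylation (7 and 21) and macrophage and Kupffer markers (1 and 8). Median, mean and test differed in sign for ATF4 and amino acid response (median 0.01, mean 0.06, camera direction down), secreted plasma carriers (median -0.10, mean 0.09, camera direction down), hepatocyte transcription factors (median 0.07, mean -0.26, camera direction down) and stellate cell and fibroblast markers (median 0.03, mean -0.10, camera direction down). Leaving out a single array ended the camera call of CAR and PXR targets (without water replicate 1, adjusted p up to 0.0563) and neuronal genes (without 10 mM replicate 3, adjusted p up to 0.0514). After quantile normalization camera no longer called CAR and PXR targets (0.222), neuronal genes (0.0546), urea cycle and ammonia (0.11) and oxidative phosphorylation (0.937, direction turned). After centring on ribosomal protein genes camera no longer called neuronal genes (0.0864) and oxidative phosphorylation (0.191). With the probesets of a gene averaged camera no longer called neuronal genes (0.0719) and oxidative phosphorylation (0.0539). With the actin ratio as a covariate camera no longer called neuronal genes (0.0533). Values in these parentheses are adjusted p. With the probesets of a gene averaged, Plin2 stood at -0.05, Fgb at -0.17, Hadha at 0.49 and Cps1 at -0.41. Plin2 stood at 0.41 after quantile normalization and at 0.35 with ribosomal centring. Cyp3a23-3a1 and Cps1 lost their calls after centring on ribosomal protein genes, Cps1 also after quantile normalization. The count was 5185 probesets higher and 3889 lower, and 6274 and 2486 with ribosomal centring.

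Whether the effect of 10 mM differed between 48 h and 24 h was tested as an interaction. It differed for 2285 probesets, 1261 with a higher effect at 48 h and 1024 with a lower one. Ribosomal centring made these 1165 and 371. Car3, a carbonic anhydrase, had an effect higher by 1.98 ± 0.15 at 48 h, and Sult1e1, an estrogen sulfotransferase, by 2.20 ± 0.25. Slc5a3, an inositol transporter, moved the other way (-1.87 ± 0.28). The fall of Cyp7a1 was smaller at 48 h (difference 1.95 ± 0.29, adjusted p = 2.27e-05). Across 11604 genes, which are not independent replicates, the effects of 10 mM at the 2 times correlated at r = 0.838. Of 4694 genes called at both times, 98.5% went the same way (2561 higher at both, against 996 for independent lists).

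The lower dose asked which genes respond at 0.5 mM. At 24 h genes of fatty acid oxidation rose. Ehhadh rose by 1.88 ± 0.12 (3.7-fold), Cyp4a1 by 1.74 ± 0.08 and the fatty acid binding protein gene Fabp1 by 1.14 ± 0.12. Of 23 mitochondrial beta-oxidation genes 19 were higher and 1 lower (camera adjusted p = 1.67e-13, and adjusted p = 0.00322 with an estimated correlation), with Acsl1 (0.92), Acadm (0.86) and Hadh (0.83), and the exception was Cpt1a at -0.47 ± 0.12. Of the PPARalpha and peroxisomal targets 16 were higher and 2 lower of 25 (camera adjusted p = 3.15e-10, and adjusted p = 0.00322 with an estimated correlation). Branched-chain amino acid catabolism had 15 of 20 higher (camera adjusted p = 2.06e-06, and adjusted p = 0.0235 with an estimated correlation), with Acad8 of valine breakdown at 0.72.

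Genes of the ATF4 and amino acid response fell at 0.5 mM and 24 h, with 22 of 29 lower and 2 higher (camera adjusted p = 2.3e-13, and adjusted p = 0.00144 with an estimated correlation). They included the arginine transporter Slc7a1 (-1.71), Chac1 (-1.31), Trib3 (-1.31) and Fgf21 (-1.31 ± 0.12). Cholesterol synthesis fell as well, with 13 of 19 lower (camera adjusted p = 1.61e-12, and adjusted p = 0.00322 with an estimated correlation), for instance Cyp51, which demethylates lanosterol (-1.17). Fasn changed by -1.02 ± 0.12, within a fatty acid synthesis list that had 10 lower and 3 higher of 22 (camera adjusted p = 0.0177, and adjusted p = 0.35 with an estimated correlation). Aryl hydrocarbon receptor targets rose (4 higher and 1 lower of 6, camera adjusted p = 0.01, and adjusted p = 0.0791 with an estimated correlation), with Cyp1a1 at 1.23 ± 0.19 and Tiparp at 0.80. Oxidative phosphorylation had 26 of 39 higher and 0 lower, with small changes (median 0.23, camera adjusted p = 4.44e-09, and adjusted p = 0.201 with an estimated correlation). The CAR and PXR list had 10 higher and 3 lower of 22 (adjusted p = 0.201 with an estimated correlation), with Cyp3a23-3a1 at 0.23 ± 0.06. Also called with the preset correlation only were Nrf2 targets (4 higher and 11 lower of 22), glutathione conjugation (11 higher and 1 lower of 23) and secreted plasma carriers (10 higher and 0 lower of 20), with adjusted p from 0.201 to 0.367 with an estimated correlation. The water arrays of this comparison had an actin log2 ratio of 1.75 ± 0.58 against 1.29 ± 0.09 with 0.5 mM.

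The largest rises at 0.5 mM and 24 h included Spc24, a kinetochore gene (2.16 ± 0.11), and Adm, the gene of the vasodilator adrenomedullin (1.85 ± 0.21), and Pck1 stood at 1.48. Histone deacetylase inhibitor genes had 6 higher and 2 lower of 19 (camera adjusted p = 0.242), and urea cycle genes 3 and 1 of 11 (camera adjusted p = 0.725), with Cps1 at 0.22 ± 0.05. Genes that missed the test at 24 h were Cyp7a1 (-0.09), Cdkn1a (-0.33), Plin2 (0.04), Alb (0.18) and Fgb (0.11). Altogether 2500 probesets were higher and 2664 lower, of which 449 changed by at least 1 on the log2 scale (270 and 179). Glucose metabolism had 5 higher and 4 lower of 18 (camera adjusted p = 0.458). Adjusted over the list alone, the counts of higher and lower members given here were the same except for mitochondrial beta-oxidation (20 and 1), PPARalpha and peroxisomal targets (17 and 3), cholesterol synthesis (0 and 14) and oxidative phosphorylation (29 and 0). Other exceptions were CAR and PXR targets (12 and 3), glutathione conjugation (13 and 1), secreted plasma carriers (14 and 0), urea cycle and ammonia (3 and 3) and glucose metabolism (7 and 4). Median, mean and test differed in sign for endoplasmic reticulum chaperones (median -0.03, mean -0.01, camera direction up) and cell cycle (median 0.05, mean -0.13, camera direction down). After quantile normalization camera no longer called fatty acid and triglyceride synthesis (0.054), CAR and PXR targets (0.123), secreted plasma carriers (0.0727) and glutathione conjugation (0.12). With the actin ratio as a covariate camera no longer called fatty acid and triglyceride synthesis (0.0859). Values in these parentheses are adjusted p. Leaving out 1 array brought a call for Alb without water replicate 5 (0.26). Cps1 and Cyp3a23-3a1 lost their calls after quantile normalization and after centring on ribosomal protein genes, Cyp3a23-3a1 also with only the compared groups in the fit. Cpt1a lost its call with the probesets of a gene averaged and with the GAPDH ratio as a covariate, and stood at -0.29 with the actin ratio. With the probesets averaged Slc7a1 stood at -0.75 and Fgb, now called, at 0.46. Plin2 stood at -0.14 after quantile normalization, a called fall. After centring on ribosomal protein genes the split was 1241 higher and 2617 lower.

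At 48 h the oxidation genes were still raised by 0.5 mM. Of 23 mitochondrial beta-oxidation genes 19 were higher and 0 lower (camera adjusted p = 1.32e-17, and adjusted p = 0.00271 with an estimated correlation), with Hadha at 0.88 and Cpt1a at 0.04 ± 0.12 (adjusted p = 0.868). PPARalpha and peroxisomal targets had 17 of 25 higher (camera adjusted p = 4.51e-11, and adjusted p = 0.00271 with an estimated correlation), with Ehhadh (2.23), Cyp4a1 (1.59) and Cpt1b (1.39). Cyp7a1 rose by 1.51 ± 0.20 (adjusted p = 1.82e-06) and the sterol hydroxylase gene Cyp8b1 by 1.09 ± 0.13, and 7 of 22 bile acid genes were higher and 2 lower (camera adjusted p = 0.0375, and adjusted p = 0.359 with an estimated correlation). Pc, the pyruvate carboxylase gene, rose by 1.75 ± 0.15 and Ero1a, an oxidase of the endoplasmic reticulum, by 1.91 ± 0.14.

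Amino acid catabolism had 17 of 30 higher at 0.5 mM and 48 h (camera adjusted p = 5.13e-06, and adjusted p = 0.126 with an estimated correlation), with Oat, the ornithine aminotransferase gene, at 1.26. Branched-chain catabolism had 11 of 20 (camera adjusted p = 5.36e-05, and adjusted p = 0.0604 with an estimated correlation) and the carnitine and coenzyme A list 11 of 24 higher (camera adjusted p = 0.000634, and adjusted p = 0.013 with an estimated correlation). The ATF4 list was lower for 13 and higher for 3 of 29 (camera adjusted p = 1.35e-05, and adjusted p = 0.041 with an estimated correlation), with Psph of serine synthesis at -1.03 and Fgf21 at -1.01 ± 0.12. Calls with the preset correlation only, besides those above, were lipid droplets and lipid export (9 higher and 2 lower of 22), cholesterol synthesis (2 higher and 9 lower of 19), CAR and PXR targets (9 higher and 2 lower of 22), other constitutive liver P450s (6 higher and 3 lower of 23), Nrf2 targets (2 higher and 7 lower of 22), glucose metabolism (9 higher and 2 lower of 18), coagulation (9 higher and 0 lower of 20), complement and acute phase (11 higher and 0 lower of 27), secreted plasma carriers (7 higher and 1 lower of 20), hepatocyte transcription factors (7 higher and 2 lower of 19), dedifferentiation associated (2 higher and 6 lower of 21) and circadian clock (2 higher and 0 lower of 16), with adjusted p from 0.159 to 0.342 with an estimated correlation. Leaving out a single array ended the camera call of cholesterol synthesis (without water replicates 2, 3, 4 and 5 or 0.5 mM replicates 2, 3 and 4, adjusted p up to 0.0837), bile acid synthesis and transport (without 0.5 mM replicate 1 or water replicate 3, adjusted p up to 0.0985), other constitutive liver P450s (without 0.5 mM replicates 1 and 2 or water replicate 3, adjusted p up to 0.124), Nrf2 targets (without water replicate 1, adjusted p up to 0.0569), hepatocyte transcription factors (without 0.5 mM replicates 1 and 4 or water replicates 2, 3 and 5, adjusted p up to 0.0852) and dedifferentiation associated (without water replicates 1 and 2 or 0.5 mM replicates 4 and 5, adjusted p up to 0.0886). After quantile normalization camera no longer called other constitutive liver P450s (0.0528). After centring on ribosomal protein genes camera no longer called cholesterol synthesis (0.163), Nrf2 targets (0.163), dedifferentiation associated (0.108) and circadian clock (0.05). With a block for each run of 6 arrays camera no longer called cholesterol synthesis (0.0543) and other constitutive liver P450s (0.0543). With the probesets of a gene averaged camera no longer called lipid droplets and lipid export (0.0974), cholesterol synthesis (0.144), hepatocyte transcription factors (0.192), dedifferentiation associated (0.338) and circadian clock (0.11). With the actin ratio as a covariate camera no longer called cholesterol synthesis (0.183), dedifferentiation associated (0.0849) and circadian clock (0.0968). Without the 3 arrays with an actin ratio above 2 camera no longer called cholesterol synthesis (0.128), hepatocyte transcription factors (0.0615), dedifferentiation associated (0.0633) and circadian clock (0.0627). Values in these parentheses are adjusted p. Among falls were Il1r2, a decoy receptor of interleukin 1 (-1.87 ± 0.21), and Gpc4, a cell-surface proteoglycan (-1.29 ± 0.06). Oxidative phosphorylation had 3 of 39 higher and 0 lower (camera adjusted p = 0.0974), and the deacetylase inhibitor list 5 higher and 1 lower of 19 (camera adjusted p = 0.272). The urea cycle list had 3 and 1 of 11 (camera adjusted p = 0.0921), AhR targets 3 and 1 of 6 (camera adjusted p = 0.0974) and p53 targets 3 and 6 of 18 (camera adjusted p = 0.0974).

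Single genes at 0.5 mM and 48 h were Cyp1a1 at 1.02 ± 0.19 and Cdkn1a at 0.47 ± 0.16, both called, and Fasn (-0.23), Plin2 (0.01), Alb (0.12), Fgb (0.11), Cps1 (0.09) and Cyp3a23-3a1 (0.07), none of them called. The counts were 2216 probesets higher and 2581 lower, and 3623 in all with the actin ratio as a covariate. Adjusted over the list alone, the counts of higher and lower members given here were the same except for mitochondrial beta-oxidation (20 and 0), PPARalpha and peroxisomal targets (18 and 4), lipid droplets and lipid export (9 and 3), cholesterol synthesis (2 and 10), bile acid synthesis and transport (7 and 5), Nrf2 targets (2 and 8) and amino acid catabolism (18 and 4). Other exceptions were branched-chain amino acid catabolism (13 and 2), coagulation (11 and 0), complement and acute phase (14 and 0), dedifferentiation associated (2 and 7), carnitine and coenzyme A (12 and 0), oxidative phosphorylation (2 and 0) and urea cycle and ammonia (4 and 2). Median, mean and test differed in sign for endoplasmic reticulum chaperones (median -0.01, mean 0.01, camera direction up) and cholangiocyte markers (median 0.04, mean -0.06, camera direction down). The actin log2 ratio was 1.82 ± 0.69 in these arrays against 1.23 ± 0.06 in water. Cdkn1a lost its call without water replicates 2, 3, 4 and 5 or 0.5 mM replicates 3, 4 and 5 (values from 0.32 to 0.61 over 10 removals), was not called in 15 alternatives in all and stood at -0.07 with the GAPDH ratio as a covariate, and Hadha lost its call with the probesets of a gene averaged. Plin2 stood at -0.32 with the probesets of a gene averaged and at 0.22 after centring on ribosomal protein genes, both called, and that centring brought calls for Alb, Fgb, Cps1 and Cyp3a23-3a1. It gave 4584 higher and 804 lower.

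The interaction test for 0.5 mM gave 4233 probesets whose effect differed between the times (2135 with a higher effect at 48 h and 2098 with a lower one). Ribosomal centring made these 4157 and 396, and at a fold of at least 2 they were 243 and 499. Cyp7a1 was among them, with a difference of 1.60 ± 0.29 (adjusted p = 0.000492), and Fasn with 0.79 ± 0.17. The largest differences were those of Inf2 (2.64), Trim36 (2.58) and Nfic (2.39) and, downward, Cryaa (-2.68) and Btc (-2.13). The groups with the uneven actin ratios enter this test on the same side. With the actin ratio as a covariate 614 probesets were called (392 higher and 222 lower), with the GAPDH ratio 204 (130 and 74), without the 3 arrays above 2 there were 1491, and without the 5 arrays with the highest ratios there were 437. The difference of Cyp7a1 was called in each of 39 alternatives, fold minimum included, and lay between 1.49 and 1.87. The calls of Fasn, Inf2, Nfic, Cryaa and Btc ended with the actin ratio as a covariate, and that of Trim36 with the GAPDH ratio.

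The doses were also compared with each other. Between 10 mM and 0.5 mM, 11086 probesets differed at 24 h (6118 higher at 10 mM) and 10040 at 48 h (5763 higher at 10 mM). With ribosomal centring 6742 were higher and 3547 lower at 24 h. Fgf21 was higher at 10 mM than at 0.5 mM by 2.15 ± 0.12 at 24 h and by 2.55 ± 0.12 at 48 h, having fallen with 0.5 mM and risen with 10 mM. Cyp1a1 went the opposite way, rising with 0.5 mM and falling with 10 mM (dose difference -2.86 ± 0.19 at 24 h and -1.91 ± 0.19 at 48 h). Cyp7a1 differed by -3.52 ± 0.20 and -3.17 ± 0.20. Cyp4a1 rose with both doses, and its dose difference was -0.39 ± 0.08 at 24 h, a call lost after quantile normalization, and 0.36 ± 0.08 at 48 h, 0.57 after that normalization.

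Across genes, which are not independent replicates, the effects of 0.5 mM and 10 mM correlated at r = 0.187 at 24 h and r = 0.098 at 48 h. Both comparisons use the same water cultures, and unchanged groups simulated against those cultures gave r = 0.502 and r = 0.499. The covariance was 0.0566 at 24 h against 0.02 simulated, and 0.0244 at 48 h against 0.0208. With the water cultures split into 2 and 3, r was 0.105 and 0.019 on average over 20 assignments. At 24 h 585 genes were higher with both doses (458 for independent lists), 732 lower with both (467), 363 higher with 0.5 mM and lower with 10 mM (368), and 529 the reverse (582). At 48 h the counts were 500 higher with both (382 for independent lists), 508 lower with both (363), 420 higher with 0.5 mM and lower with 10 mM (308) and 510 the reverse (450). Split water cultures gave on average 299 higher with both, 427 lower with both and 546 opposite at 24 h, and 249, 259 and 513 at 48 h. Same-direction genes made up 59.6% of those called with both doses at 24 h and 52% at 48 h.

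**Figure D2:**
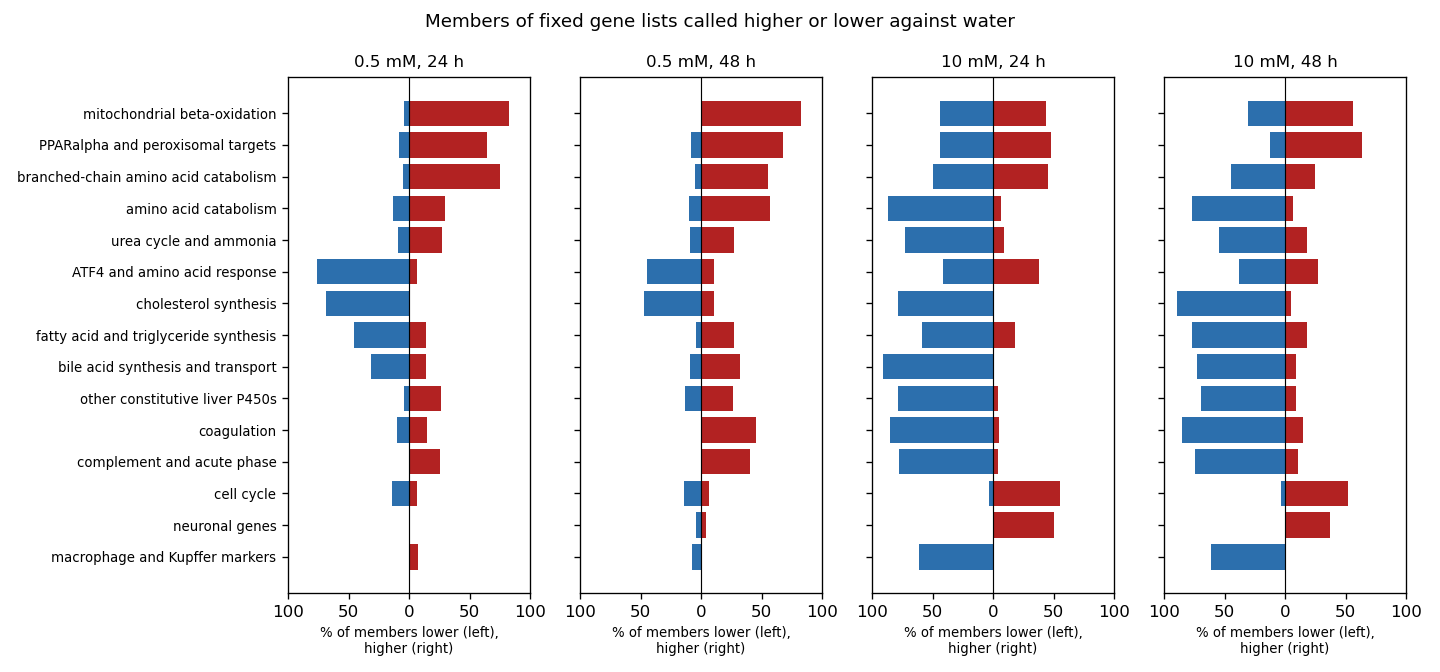
Percent of the measured members of 15 fixed gene lists (vertical axis) called higher (red, to the right) or lower (blue, to the left) than water in each of 4 valproate comparisons (panels). Beta-oxidation genes are mostly red at 0.5 mM, and bile acid, P450 and coagulation genes mostly blue at 10 mM.

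Water cultures drifted between 24 h and 48 h. Serpina3c, a serine protease inhibitor gene, changed by -2.63 ± 0.16, Serpina6, the corticosteroid-binding globulin gene, by -2.03 ± 0.14 and Cyp1a2, a liver P450, by -1.78 ± 0.12. Tsx rose by 1.99 ± 0.19 and Cd36, a fatty acid uptake gene, by 1.47 ± 0.23 (0.94 with the actin ratio as a covariate and 0.87 with the GAPDH ratio). Complement and acute phase genes were lower for 12 of 27 (camera adjusted p = 4.13e-12, and adjusted p = 0.0545 with an estimated correlation). Coagulation genes were lower for 11 of 20 (camera adjusted p = 2.04e-09, and adjusted p = 0.0803 with an estimated correlation) and amino acid catabolism genes for 10 of 30 (camera adjusted p = 1.37e-05, and adjusted p = 0.0888 with an estimated correlation). Dedifferentiation genes were higher for 6 of 21 (camera adjusted p = 5.05e-05, and adjusted p = 0.0888 with an estimated correlation). Also called between the times in water with the preset correlation only were PPARalpha and peroxisomal targets (6 higher and 0 lower of 25), cholesterol synthesis (0 higher and 6 lower of 19), bile acid synthesis and transport (1 higher and 3 lower of 22), CAR and PXR targets (0 higher and 6 lower of 22), other constitutive liver P450s (2 higher and 8 lower of 23), endoplasmic reticulum chaperones (0 higher and 6 lower of 22), urea cycle and ammonia (0 higher and 2 lower of 11), glucose metabolism (0 higher and 6 lower of 18), secreted plasma carriers (1 higher and 4 lower of 20), hepatocyte transcription factors (0 higher and 2 lower of 19), circadian clock (0 higher and 3 lower of 16), macrophage and Kupffer markers (0 higher and 1 lower of 13) and cholangiocyte markers (2 higher and 0 lower of 6), with adjusted p from 0.0545 to 0.233 with an estimated correlation. With camera and an estimated correlation 0 of 35 lists passed, 11 had an unadjusted p under 0.05, and fry called 22. Leaving out a single array ended the camera call of urea cycle and ammonia (without 48 h water replicate 3, adjusted p up to 0.0646), hepatocyte transcription factors (without 24 h water replicate 4, adjusted p up to 0.0705) and macrophage and Kupffer markers (without 48 h water replicate 2, adjusted p up to 0.0568). With the probesets of a gene averaged camera no longer called urea cycle and ammonia (0.0792) and hepatocyte transcription factors (0.0809). Without the 3 arrays with an actin ratio above 2 camera no longer called macrophage and Kupffer markers (0.0516). Values in these parentheses are adjusted p. Adjusted over the list alone, the counts of higher and lower members given here were the same except for PPARalpha and peroxisomal targets (8 and 0), cholesterol synthesis (0 and 9), bile acid synthesis and transport (1 and 5), other constitutive liver P450s (3 and 10), endoplasmic reticulum chaperones (0 and 9), urea cycle and ammonia (0 and 4) and amino acid catabolism (3 and 13). Other exceptions were glucose metabolism (2 and 7), coagulation (0 and 13), complement and acute phase (1 and 17), secreted plasma carriers (1 and 6), hepatocyte transcription factors (0 and 4), dedifferentiation associated (8 and 0) and cholangiocyte markers (3 and 0). The actin log2 ratio was 1.75 ± 0.58 at 24 h and 1.23 ± 0.06 at 48 h. In all 853 probesets were higher and 835 lower at 48 h, 195 and 1127 after centring on ribosomal protein genes.

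**Figure D3:**
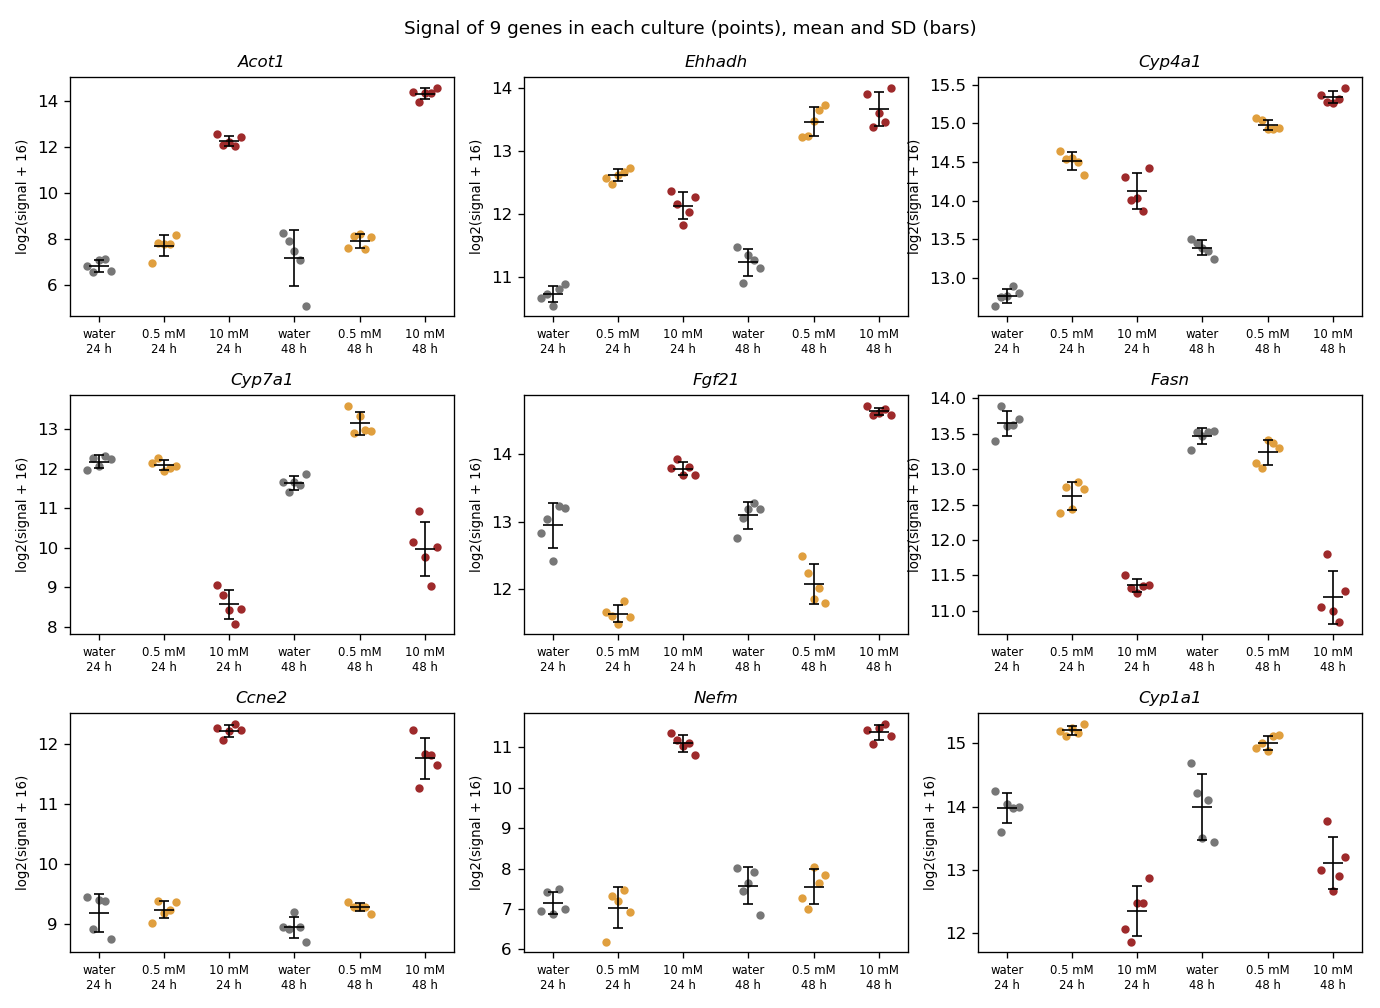
Log2(signal + 16) of 9 genes (vertical axes) in each culture (points) of the 6 groups (horizontal axes), with mean and SD as bars. Ehhadh and Cyp4a1 lie higher with both doses, while Fgf21 and Cyp1a1 move in opposite directions at 0.5 mM and 10 mM.

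At 10 mM macrophage and Kupffer cell markers were lower for 8 of 13 members at 24 h (camera adjusted p = 0.00428, and adjusted p = 0.0363 with an estimated correlation) and 8 at 48 h (camera adjusted p = 0.00287, and adjusted p = 0.0338 with an estimated correlation), with the complement gene C1qc at -2.17 and the endotoxin co-receptor gene Cd14 at -2.06 at 24 h. Bile duct cell markers were lower for 3 of 6 at 24 h (camera adjusted p = 0.22) and 4 at 48 h (camera adjusted p = 0.00628, and adjusted p = 0.043 with an estimated correlation). Fibroblast and stellate cell markers had 2 higher and 5 lower of 14 at 24 h (camera adjusted p = 0.352), with Col3a1 at -0.73, and endothelial markers 0 higher and 3 lower of 9 (camera adjusted p = 0.176), with Fcgr2b at -3.03. At 0.5 mM none of the 4 lists of other cell types passed camera, with adjusted p from 0.084 to 0.304 at 24 h and from 0.503 to 0.839 at 48 h. At 10 mM and 48 h fibroblast markers had camera adjusted p = 0.475 and endothelial markers 0.196.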

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

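In this part the tests with RNA quality as a covariate, with quantile normalization and with markers of other cells were chosen only after the result was seen, and the removals of matched arrays were ranked after the count without the 5 arrays was known.

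Single arrays stood apart for some of the 121 genes examined and 3 array measures. In 45 of 744 comparisons of 5 arrays, the gap between the highest or lowest array and its neighbour took up more of the group's range than Dixon's 95% limit allows, where chance gives about 1 in 20 (37.2). The share of the range is given with each gene. Replicate 2 of water at 24 h lay above the others for Mbl2 (0.732) and below them for Cryaa (0.795) and Cyp1a2 (0.827). Replicate 3 of water at 24 h lay above the others for Abcc3 (0.746), Angptl4 (0.73), Atf3 (0.854), Ftcd (0.761), Hal (0.802), Sardh (0.753) and the actin 3'/5' log2 ratio (0.76). It lay below them for Cd36 (0.739), Otc (0.746) and Sult1e1 (0.783). Replicate 4 of water at 24 h lay below the others for Crip1 (0.77). Replicate 1 of 0.5 mM at 24 h lay above the others for Fabp1 (0.766). Replicate 4 of 0.5 mM at 24 h lay above the others for Por (0.901) and below them for Ccne1 (0.714). Replicate 5 of 0.5 mM at 24 h lay below the others for Car3 (0.838), Cdkn1a (0.789) and the GAPDH 3'/5' log2 ratio (0.778). Replicate 1 of 10 mM at 24 h lay above the others for Baat (0.736) and below them for Abcc3 (0.713) and Alb (0.803). Replicate 3 of 10 mM at 24 h lay above the others for Serpind1 (0.896). Replicate 5 of 10 mM at 24 h lay above the others for Slc27a5 (0.797). It lay below them for Hspb1 (0.735), Mcm4 (0.739), Trib3 (0.882) and the GAPDH 3'/5' log2 ratio (0.833). Replicate 1 of water at 48 h lay above the others for Cyp1a2 (0.819) and the actin 3'/5' log2 ratio (0.784). It lay below them for Cyp51 (0.796) and Fasn (0.736). Replicate 4 of water at 48 h lay above the others for Inf2 (0.841). Replicate 1 of 0.5 mM at 48 h lay below the others for Slc16a3 (0.752). Replicate 5 of 0.5 mM at 48 h lay below the others for Fcgr2b (0.711). Replicate 1 of 10 mM at 48 h lay below the others for Btc (0.764). Replicate 2 of 10 mM at 48 h lay above the others for Abcc3 (0.781) and Glyat (0.807). It lay below them for Bhlhe41 (0.811), Cd24 (0.842), Slc2a1 (0.835) and Uchl1 (0.886). Replicate 3 of 10 mM at 48 h lay below the others for Bnip3 (0.723). Replicate 5 of 10 mM at 48 h lay above the others for Cyp3a23-3a1 (0.724). Replicate 3 of water at 24 h, the array with an actin ratio of 2.76, had 10 of these.

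Effects of valproate differed between the times by limma's interaction test for 57 of 121 examined genes at 10 mM. The log2 effect was higher at 48 h than at 24 h, by at least 1, for Sult1e1 (2.20), Car3 (1.98), Tmed1 (1.97), Fabp1 (1.96), Cyp7a1 (1.95), Serpina6 (1.90), Hal (1.73), Cyp3a2 (1.70), Acot1 (1.70), Igfbp2 (1.55), Serpina3c (1.49), Crip1 (1.41), Cyp8b1 (1.36), Baat (1.32), Cyp2b3 (1.20), Chdh (1.11), Nr1h3 (1.11), Ehhadh (1.04), Mt1 (1.03), Sardh (1.03) and Pck1 (1.01). Differences between 0.7 and 1 were those of Mat1a (0.99), Pc (0.98), Glyat (0.93), Spc24 (0.93), Cyp2f4 (0.87), Acadvl (0.86), Arg1 (0.85), Serpind1 (0.83), Cyp2a2 (0.76) and Slco1a4 (0.72). Smaller ones were those of Fgf21 (0.70), Cpt1b (0.68), Mbl2 (0.67), Hspb1 (0.61), Nr1i3 (0.61), Acaca (0.60), Cyp4a1 (0.59), Gpc4 (0.57), Hamp (0.56), Ak4 (0.51), Slc25a15 (0.51), Hadha (0.47), Fgb (0.39) and Acsl1 (0.35). At 48 h the effect was lower by less than 1 for Ddit3 (-0.48), Acad8 (-0.55), Pdk4 (-0.59), Slc27a5 (-0.59), Bnip3 (-0.70), Slc16a3 (-0.83) and Defb1 (-0.95). Larger negative differences were those of Atf3 (-1.04), Slc2a1 (-1.06), Adm (-1.40), Slc5a3 (-1.87) and Tsx (-1.90). Of the 57 calls 18 ended in at least 1 alternative, the fold minimum aside. Leaving out 1 array ended those of Acsl1 (without 48 h 10 mM replicates 1 and 5 or 24 h water replicate 2 or 24 h 10 mM replicates 3 and 4 or 48 h water replicate 3, 0.30 to 0.39), Defb1 (without 48 h water replicate 1 or 48 h 10 mM replicates 1 and 4, -1.23 to -0.78), Igfbp2 (without 24 h water replicates 1, 2 and 5 or 24 h 10 mM replicates 1, 2 and 3 or 48 h water replicates 1, 4 and 5 or 48 h 10 mM replicates 1, 4 and 5, 1.26 to 1.84), Nr1i3 (without 24 h water replicates 1, 4 and 5 or 48 h 10 mM replicates 1, 2 and 5 or 24 h 10 mM replicates 2, 4 and 5 or 48 h water replicates 2, 3, 4 and 5, 0.51 to 0.69), Slc16a3 (without 48 h 10 mM replicates 2 and 3 or 24 h water replicates 4 and 5 or 24 h 10 mM replicate 5 or 48 h water replicate 5, -0.93 to -0.69), Slc25a15 (without 48 h 10 mM replicate 2 or 24 h water replicate 3 or 48 h water replicate 3 or 24 h 10 mM replicate 4, 0.38 to 0.58) and Slco1a4 (without 48 h water replicate 1 or 48 h 10 mM replicate 1 or 24 h water replicate 2 or 24 h 10 mM replicates 2, 3 and 5, 0.50 to 0.87), with the range over all removals.

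At 0.5 mM the effect differed between the times for 39 of the genes. The log2 effect was higher at 48 h, by at least 1, for Inf2 (2.64), Trim36 (2.58), Nfic (2.39), Cyp7a1 (1.60), Pc (1.24) and Slc7a1 (1.00). Differences between 0.7 and 1 belonged to Mat1a (0.99), Cyp3a2 (0.94), Sardh (0.92), Acaca (0.82), Chdh (0.81), Cdkn1a (0.80), Fasn (0.79), Sqle (0.74) and Trib3 (0.73). Smaller ones belonged to Vegfa (0.70), Cyp51 (0.67), Ak4 (0.62), Hal (0.61), Por (0.57), Chac1 (0.56), Cyp1a2 (0.52), Mxi1 (0.51), Cpt1a (0.51), Hadha (0.49), Cpt1b (0.45), Cyp2a2 (0.44) and Acadvl (0.34). The effect was lower at 48 h by less than 1 for Bnip3 (-0.48), Hamp (-0.48), Acad8 (-0.49), Gadd45a (-0.65), Adm (-0.86) and Tsx (-0.91), and by more for Cd36 (-1.13), Hdac1 (-1.16), Il1r2 (-1.50), Btc (-2.13) and Cryaa (-2.68). Among the arrays of this test the actin log2 ratio was 1.75 ± 0.58 in water at 24 h and 1.82 ± 0.69 with 0.5 mM at 48 h, against 1.29 ± 0.09 and 1.23 ± 0.06 in the other groups (SD, n = 5). Of the 39 calls 34 ended in at least 1 alternative, the fold minimum aside, 25 with the actin ratio as a covariate, 31 with the GAPDH ratio, 20 without the 3 arrays with an actin ratio above 2 and 29 without the 5 with the highest. Leaving out 1 array ended those of Cpt1a (without 24 h water replicates 1, 2 and 3 or 24 h 0.5 mM replicate 1 or 48 h water replicates 3, 4 and 5 or 48 h 0.5 mM replicates 3 and 4, 0.36 to 0.60), Adm (without 24 h 0.5 mM replicates 1, 2, 3 and 4 or 48 h water replicates 1, 2 and 4 or 24 h water replicates 2 and 3 or 48 h 0.5 mM replicates 3 and 4, -1.04 to -0.67), Cpt1b (without 48 h 0.5 mM replicate 3, 0.39 to 0.54), Cyp1a2 (without 48 h water replicates 4 and 5 or 48 h 0.5 mM replicate 5, 0.47 to 0.64), Gadd45a (without 24 h water replicates 1 and 3 or 24 h 0.5 mM replicates 1, 2, 3 and 4 or 48 h water replicates 2, 3, 4 and 5 or 48 h 0.5 mM replicates 3, 4 and 5, -0.80 to -0.47), Hal (without 24 h water replicate 3 or 24 h 0.5 mM replicate 3 or 48 h 0.5 mM replicate 3, 0.50 to 0.68) and Hamp (without 48 h water replicate 1 or 24 h 0.5 mM replicate 2, -0.56 to -0.41), with the range over all removals.

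The 4233 probesets whose 0.5 mM effect differed between the times were weighed against RNA quality and scaling. Quantile normalization gave 4148 and ribosomal centring 4157 higher, 396 lower, so scaling affects direction. With the actin ratio as a covariate 614 were called, and without the 5 arrays with the highest ratios 437, a count that only 3 of 100 removals of as many arrays from the same groups matched or undercut, itself included (median 2746, lowest other 243, highest 6974). RNA quality of those 0.5 mM arrays is a candidate cause. A real difference between the times stays open, and the Cyp7a1 difference was called in each of 39 alternatives.

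Cell cycle genes rose at 10 mM and 24 h (camera adjusted p = 0.00428, and adjusted p = 0.0626 with an estimated correlation). Macrophage markers, which a smaller share of hepatocytes could raise, fell (median -0.605, camera adjusted p = 0.00428). The fibroblast marker median was -0.097 (95% bootstrap interval -0.734 to 0.261), against 0.858 for cell cycle genes. As 10 mM may change marker genes itself, neither excludes a shift in cell types. After quantile normalization camera gave adjusted p = 0.0173 for the list, and with the actin ratio as a covariate 0.00529. The rise may be a response of the hepatocytes to 10 mM, a hypothesis found and tested on the same arrays.

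Chance assignment of samples to groups was examined with 100 splits per comparison. Only the real split reached its count in each, 1 of 100, the lowest share that 100 splits can give. Other splits mix the groups, and none can tell an effect of valproate from that of a plate. Real counts against the highest other split were 10483 against 5112 for 10 mM at 24 h, 9074 against 5123 for 10 mM at 48 h, 5164 against 758 for 0.5 mM at 24 h and 4797 against 3099 for 0.5 mM at 48 h. They were 2285 against 1286 and 4233 against 462 for the differences between times at 10 mM and 0.5 mM. They were 11086 against 5617 and 10040 against 6079 between the doses at 24 h and 48 h, and 1688 against 116 between the times in water.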

How the results depend on the processing

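The RNA-quality alternatives (actin, GAPDH, left-out arrays by actin ratio, residual scores) and the list tests on the time differences were chosen after seeing the data, and the other alternatives before. Of alternative values for single genes and lists, 23016 kept direction and side of the threshold, 897 lost the call, 329 gained it and 24 turned direction. Of counts, list totals and correlations, 390 alternatives stayed close and the others are given here. With a fold minimum of 2, which by construction removes small changes, the counts in the order 10 mM at 24 h and 48 h, 0.5 mM at 24 h and 48 h, time differences at 10 mM and 0.5 mM, doses at 24 h and 48 h, and water were 2966, 2038, 449, 430, 330, 742, 3097, 2658 and 111. With the mean of the probesets of a gene, where fewer features are tested, the first 8 were 5951, 5298, 2958, 2892, 1355, 2157, 6243 and 5770. For the 0.5 mM time difference (4233) there were 2817 with only the compared groups, 614 with actin, 204 with GAPDH, 1491 without 3 arrays, 437 without 5 and 1068 with the first residual score. For 0.5 mM at 48 h there were 2946 with GAPDH and 2625 without 5 arrays. The times in water gave 1047 with only the compared groups, 963 with GAPDH and 3347 with the centred residual score. That score gave 3719 for the 10 mM time difference. By construction the centred score changes no effect and only removes residual variance. Fits of only the compared groups alter residual variance and its degrees of freedom, not effects. The cause of the other shifts was not settled. Leaving out 1 array moved no count by over 1.5 times, with 3107 to 5283 for the 0.5 mM time difference, 3936 to 5483 for 0.5 mM at 48 h and 1139 to 1968 for the times in water.

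Lists called with an estimated correlation numbered 7 and 6 at 10 mM (24 h and 48 h), 5 and 4 at 0.5 mM and 0 for the times in water (camera, 11 at an unadjusted p under 0.05), against 21, 19, 12, 19 and 17 with the preset. For the time differences they were 7 of 11 at 10 mM and 0 of 7 at 0.5 mM (camera, 4 unadjusted). Fry, which compares a list with no other genes, called 32 and 32 at 10 mM, 23 at 0.5 mM and 24 h, and 16 and 10 for the time differences. Ribosomal centring gave 13 lists for the 0.5 mM time difference. The correlation of the 0.5 mM and 10 mM effects at 24 h was 0.143 with quantile normalization, and 0.105 at 24 h and 0.019 at 48 h with the water samples split. Oxidative phosphorylation turned direction with quantile normalization at 10 mM (camera adjusted p = 0.575 at 24 h and 0.937 at 48 h).

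Genes that turned direction were counted in the same way, with a call in the main or the alternative fit. With quantile normalization they were Plin2 for 0.5 mM at 24 h (-0.14), Plin2 for the 0.5 mM time difference (0.15) and Alb for the doses at 24 h (0.0128). With ribosomal centring Plin2 turned for the 0.5 mM time difference (0.25). With the mean of probesets they were Fgb and Plin2 for 10 mM at 48 h (-0.17 and -0.0543). Plin2 also turned for 0.5 mM at 48 h (-0.32), and Fgb for the 10 mM time difference (-0.49) and the doses at 48 h (-0.14). For the 0.5 mM time difference Cpt1a (-0.0703), Hadha (-0.23), Mxi1 (-0.34) and Vegfa (-0.0822) turned. With GAPDH they were Hdac1 for 0.5 mM at 24 h (-0.35) and Cdkn1a for 0.5 mM at 48 h (-0.0684). For the 0.5 mM time difference GAPDH turned Cdkn1a (-0.12), Cd36 (0.20), Gadd45a (0.14) and Hdac1 (0.30). Gadd45a also turned there with actin (0.0119) and without 5 arrays (0.0186). Inf2 turned without 5 arrays for 0.5 mM at 48 h (-0.16). The cause was not tested. Splits of higher and lower probesets moved by over 10 percentage points, among the scalings, with ribosomal centring only, here with the deposited scaling in parentheses, for 10 mM at 48 h 6274 and 2486 (5185 and 3889), 0.5 mM at 24 h 1241 and 2617 (2500 and 2664), 0.5 mM at 48 h 4584 and 804 (2216 and 2581), the 10 mM time difference 1165 and 371 (1261 and 1024), the 0.5 mM time difference 4157 and 396 (2135 and 2098), the doses at 24 h 6742 and 3547 (6118 and 4968) and the times in water 195 and 1127 (853 and 835). They also moved so with the fold minimum for 0.5 mM at 24 h (270 and 179) and, for the 0.5 mM time difference, with the fold minimum (243 and 499), actin (392 and 222) and GAPDH (130 and 74). With quantile normalization the median change of all probesets moved by over 0.1 on the log2 scale for 10 mM at 24 h (-0.008 from 0.099). With ribosomal centring it moved so for 10 mM at 48 h (0.171 from 0.036) and 0.5 mM at 48 h (0.205 from -0.004). The 0.5 mM time difference (0.202 from -0.075), doses at 24 h (0.103 from -0.008) and times in water (-0.076 from 0.04) moved so too. A block for each run of 6 arrays gave 4337 for the 0.5 mM time difference, and 1 of 75 pairs of arrays in a run deviated together with r over 0.1. The labels give no shared replicate numbers. Signal near background limits what could be detected for dim probesets.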

Other observations

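The tests of gene lists on the time differences were chosen only after the results at single times were seen, and the oxygen-responsive list was written after Adm and other large rises were seen but before the values of its members were looked at. With 10 mM, several metabolic gene lists had higher effects at 48 h than at 24 h, that is, less negative or more positive changes. The effect on PPARalpha and peroxisomal targets was higher at 48 h for 18 and lower for 1 of 25 members, with a median difference of 0.43 (camera adjusted p = 8.7e-13, and adjusted p = 0.00196 with an estimated correlation). CAR and PXR targets had 10 of 22 with a higher effect at 48 h and carnitine and coenzyme A genes 6 of 24. Hepatocyte transcription factors had 6 of 19. With an estimated correlation camera adjusted p was 0.0118, 0.00392 and 0.0201. Bile acid genes (10 of 22), amino acid catabolism (10 of 30) and lipid droplet genes (6 of 22) also had higher effects at 48 h. Each had camera adjusted p = 0.048 with an estimated correlation. The other 4 of 11 lists with a camera call were mitochondrial beta-oxidation (9 higher and 0 lower of 23, median 0.19), Nrf2 targets (7 higher and 1 lower of 22, median 0.16), urea cycle and ammonia (4 higher and 0 lower of 11, median 0.21) and cholangiocyte markers (0 higher and 1 lower of 6, median -0.58), with adjusted p from 0.0556 to 0.315 with an estimated correlation. At 0.5 mM the cholesterol synthesis effect was higher at 48 h for 10 of 19 members, called with the preset correlation only (adjusted p = 0.11 with an estimated correlation). Actin ratios were uneven among the arrays of this test, and camera gave adjusted p = 4.05e-17 with the ratio as a covariate and adjusted p = 3.85e-12 without the 3 arrays above 2, direction up in both. Of 7 lists called at 0.5 mM, 0 passed with camera and an estimated correlation, 4 had an unadjusted p under 0.05 there, and fry called 10.

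Genes known to respond to low oxygen stood among the large rises at 0.5 mM, and were named after their values were seen. Stc1, a calcium regulator, rose by 1.36 ± 0.24 at 24 h and 1.89 ± 0.24 at 48 h, Ndrg1 by 1.52 ± 0.18 and 1.41 ± 0.18, and Vegfa, the angiogenic factor gene, by 0.60 ± 0.13 and 1.30 ± 0.13. Cited2, a regulator of the hypoxia response, rose by 1.36 ± 0.17 and 1.16 ± 0.17 with 0.5 mM and changed by -1.29 ± 0.17 and -1.58 ± 0.17 with 10 mM. A separate list of 33 oxygen-responsive genes, 28 of them measured, tested the hypothesis that such genes rise as a group, with p adjusted over 4 comparisons.

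With 0.5 mM, 18 members of that list were higher and 0 lower at 24 h (median 0.30, camera p = 1.99e-08, and adjusted p = 0.0502 with an estimated correlation, which misses the threshold). At 48 h 16 were higher and 0 lower (median 0.24, camera p = 1.21e-07, and adjusted p = 0.0502 with an estimated correlation, which misses the threshold). Members included Egln3, an oxygen sensor (1.15 and 1.24), the glucose transporter Slc2a1 (0.70 and 0.46) and the lactate transporter Slc16a3 (0.84 and 0.72). The 48 h calls of Slc2a1 and Slc16a3 ended with the GAPDH ratio as a covariate and without the 5 arrays with the highest actin ratios. Slc2a1 was not called in 6 alternatives, the fold minimum aside, the actin ratio as a covariate among them (0.29). With the actin ratio as a covariate the list kept its upward direction at both times (camera adjusted p = 9.96e-10 and adjusted p = 1.51e-06). With 10 mM, 11 members were higher and 9 lower at 24 h (median -0.062, camera direction up, camera adjusted p = 0.62), and 7 and 11 at 48 h (camera adjusted p = 0.188). The 0.5 mM cultures may have had less oxygen or a stronger response to it, a hypothesis that stays open because oxygen was not measured.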
